A study of Heyndrickxia coagulans with 2 samples.

How the data were processed

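RNA was sequenced in 2 libraries of Heyndrickxia coagulans, a Gram-positive, spore-forming, lactic acid-producing bacterium formerly named Bacillus coagulans. Per the labels' protocols, the bacteria came from a capsule, the cultures were 18 h old, RNA was stabilised at harvest and treated on the column to remove DNA, and samples with an RNA integrity number above 6 were kept. Messenger RNA was enriched with magnetic beads, and uracil was placed in the second cDNA strand. The plan was 40 M paired reads of 150 bp per sample. One library, ED1, carries the label of nanoparticle treatment. The treatment label of the other, EA1, only repeats its name. The series design speaks of control and treated bacteria, so EA1 is the control by elimination, and it is called EA1 here. The metal oxide, its dose and the exposure time are not given in the sources used here.

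The authors deposited a table of 3175 genes with a locus identifier, a position on 1 of 179 numbered contigs and a signal per library, which the file's own description calls a mean expression value. The aligner, counter, genome assembly and scaling are not given in the sources used here. That description names the condition of the ED1 column as EB1. The column was taken as ED1 from its header, and this mismatch remains open. In each library every value was a whole multiple of 1 step to within 0.001 of a step (100% of values), with a step of 1.60 in EA1 and 1.15 in ED1. One step was taken as 1 read, which puts the depth at 19.0 M reads on listed genes in EA1 and 21.9 M in the nanoparticle library. The lowest listed gene had 2 reads in EA1 and 3 in the nanoparticle library, and no gene was listed at 0. The deposited signal is therefore proportional to reads per gene, without a correction for gene length. A trimmed mean of log ratios (30% of log ratios and 5% of abundances trimmed) computed from those reads gave the same relative scaling as the deposited signal to 2 decimals on the log2 scale (a shift of -6.7e-12).

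The authors' deposited table also gives a log2 ratio of the conditions, coded as EA1 over ED1, their difference as a signal, a probability of differential expression as a fraction from 0 to 1, and a ranking score. Recomputing the log2 ratio from the signals matched the deposited values to within 0.0001. A second table holds the 499 genes with a probability of at least 0.8. Another table, deposited by the authors, gives a p-value and an adjusted p-value for 199 GO terms and lists the called genes under each term. The test, the background and the tool behind these p-values are not given in the sources used here. Columns of other samples left unused numbered 0.

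Ratios are given here as log2 of nanoparticle over EA1 on the log2(value + 1) scale, so a positive value is higher in the nanoparticle library and has the opposite sign to the deposited log2 ratio. Genes were ranked only where the mean of both libraries was at least the 25th percentile of all genes (285.9 scaled reads), which kept 2381 genes. With 1 library per group there are no residual degrees of freedom, so no p-value was computed, and a rule of size (at least 2-fold) was used in its place. Ratios carry 95% exact (Clopper-Pearson) intervals from the recovered reads. These intervals cover counting error only: reads carry no molecular identifiers, and the intervals hold no spread between cultures or library preparations. On simulated pairs of libraries drawn from the real means, with 3175 genes, the 2-fold rule called 100% of 100 genes changed 3-fold, 0% of 100 genes changed 1.5-fold and 0 of 2189 unchanged genes, and the 95% interval covered 0 for 95.0% of 2975 unchanged genes. That simulation held counting error alone.

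Before the data were examined, 20 gene lists were fixed by gene symbol and product name. The files pair locus identifiers with neither, so none of the lists could be matched. GO terms of the authors' enrichment table whose names correspond to the lists were used in their place, which was decided after the values were seen. That table lists 209 of the 499 called genes under at least 1 term. A GO group here thus holds only genes the authors had already called, and says nothing of members that were not called. The group's median was placed among the medians of 10000 random lists of the same size drawn from the 209 genes, matched on deciles of mean expression. Of those 209 genes, 86 were higher and 123 lower, so a group of higher genes looks more extreme than in an even pool. The 44 terms with at least 3 genes were all placed, with no allowance for their number. The plan placed only lists of at least 5 members, and groups of 3 or 4 genes were placed as well after the values were seen. Matching on 5 bins, also tried after the data were seen, put the sugar phosphotransferase system at percentile 98.0. The lists draw genes singly, so a group of neighbours that differ together looks more extreme than it is, and no percentile is given for the whole ribosome and glycolytic sets. The percentile describes these 2 libraries, and genes are not replicates. The rule for named features, fixed in advance for files without gene names, was the 2 identifiers with the largest and the 2 with the smallest ratio above the floor. Other genes are described by their GO term or position and were chosen after their values were seen.

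The alternatives were scaling by total reads, by the median of ratios, by the trimmed mean and by total reads without the most abundant feature, other floors, pseudocounts of 0.1, 5 and 10, a 4-fold rule, and stricter probabilities on the authors' calls. Reads and genomic sequence were not used here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.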

Results

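The transcriptome of Heyndrickxia coagulans was compared between a culture treated with a metal oxide nanoparticle and a second culture, EA1, which is the control by elimination. Each condition was represented by 1 library, so every ratio compares these 2 libraries and has no replicate check. Reads on the 3175 listed genes numbered 19014590 in EA1 and 21853727 in the nanoparticle library, with a median of 930 and 1319 reads per gene. Positions are given on the numbered contigs of the authors' table, whose assembly is not named in the sources used here.

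The comparison addressed how gene expression differed when the bacteria met the nanoparticle. Among genes the authors had called, most of those listed for ribosome structure and all of those listed for a glycolytic enzyme were lower in the nanoparticle library. All called genes listed for the sugar phosphotransferase system were higher. Most ratios were small. Of the 2381 genes above the abundance floor, 1918 (80.6%) differed by less than 1.25-fold, and the log2 ratios had a median of 0.01 and an SD of 0.26 across genes. At least 1.5-fold, 23 genes were higher and 47 lower in the nanoparticle library. At least 2-fold, 1 gene was higher and 1 lower. These counts depended on the processing: scaling by total reads gave 7 higher and 0 lower, and a floor of 200 reads over both libraries gave 4 and 6. Without the floor, 27 genes were at least 2-fold higher and 47 at least 2-fold lower, and 26 and 46 of these lay in the lowest 25% of genes by abundance, where counting error alone gave an SD of 0.31 on the log2 scale against an observed 0.58.

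Across the 4 features named by rule, the largest ratio above the floor belonged to IE89_13915, an 87 bp feature on contig123 from 5433 to 5519. It had 725 scaled reads in EA1 and 1974 in the nanoparticle library, a log2 ratio of 1.44 (95% counting interval 1.294 to 1.597), and no GO term in the enrichment table. This feature is shorter than a planned read of 150 bp. How reads were assigned to it is not given in the sources used here, and the interval does not cover that step. IE89_01180 (contig7, 39396 to 40469), listed under cytochrome-c oxidase activity and copper ion binding, was 1.99-fold higher, with a log2 ratio of 0.99 (95% counting interval 0.90 to 1.08). Cytochrome-c oxidase is a terminal oxidase of aerobic respiration. The lowest ratio above the floor belonged to IE89_17100, a 407 bp feature on contig136 from 12885 to 13291 with no GO term. Its log2 ratio was -1.11 (95% counting interval -1.11 to -1.10). IE89_08595 (contig69, 12248 to 12448), a gene of 201 bp listed for ribosome structure, was 1.93-fold lower, with a log2 ratio of -0.95 (95% counting interval -0.97 to -0.94).

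IE89_17100 was the most abundant feature of both libraries. It took 29.3% of the reads on listed genes in EA1 (exact 95% interval 29.29% to 29.33%) and 16.5% in the nanoparticle library (16.48% to 16.51%). Its share affects any scaling by total reads: with that scaling the log2 ratio of every gene was 0.28 higher than with the deposited scaling, and without this feature in the totals the shift was 0.04. The directions given here are relative to the deposited scaling, in which the median gene lies at 0.01.

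**Figure D1:**
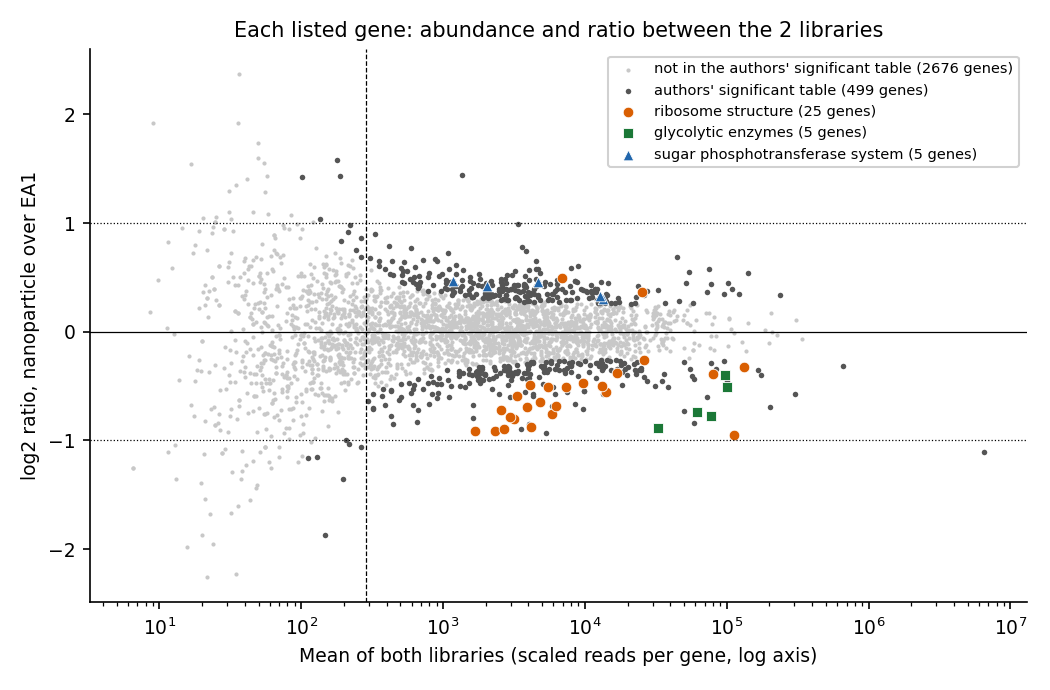
Each point is 1 of the 3175 listed genes, with the mean of both libraries in scaled reads on a log axis and the log2 ratio of nanoparticle over EA1 on the vertical axis; dotted lines mark 2-fold and the dashed line the abundance floor. Genes listed for ribosome structure (orange circles) lie below 0 in 23 of 25 cases, the 5 glycolytic enzyme genes (green squares) all lie below 0, and the 5 sugar phosphotransferase genes (blue triangles) all lie above 0.

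The authors' deposited table called 499 genes at a probability of at least 0.8, of which 253 were higher and 246 lower in the nanoparticle library. Their median ratio was 1.33-fold, 412 of them differed by less than 1.5-fold, and 13 differed by at least 2-fold. Those 13 were mostly of low abundance, with a median of 291 reads over both libraries against 5626 for all 499. Under scaling by total reads the same 499 genes divided into 266 above and 233 below 0. With 1 library per condition, that probability rests on no spread between cultures.

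Genes for the ribosome, the machine of protein synthesis, formed the largest group that was lower. Of the 25 called genes listed for ribosome structure, 23 were lower and 2 higher in the nanoparticle library, with a median log2 ratio of -0.59, or 1.51-fold lower. On contig60 lay 19 of the 25 genes, and all 19 were lower, with a median of -0.69. The other 6 genes were 4 lower and 2 higher, with a median of -0.29 that stood at percentile 72.4 of random lists. The 2 higher genes were one on contig64 (29224 to 29511, log2 ratio 0.37, 95% counting interval 0.34 to 0.40) and one on contig95 (11792 to 11977, 0.50, 0.44 to 0.56). All members were chosen for having been called, and 18 of the 25 sat in 1 row of neighbours, so the group does not stand for 25 separate differences.

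Of 13 called genes listed for RNA binding, some of them also listed for ribosome structure, 12 were lower and 1 higher. Their median log2 ratio of -0.47 stood at percentile 2.95, just within the 95% range of random lists (-0.48 to 0.34). The lowest, on contig63, was at -0.84 and had no other term. All 3 called genes listed for tRNA ligases, the enzymes that charge tRNAs with amino acids, were lower. The gene listed for alanine-tRNA ligase had a log2 ratio of -0.36 (95% counting interval -0.45 to -0.28) and that for cysteine-tRNA ligase -0.42 (-0.50 to -0.35). Their median, -0.36, stood at percentile 41.6, well within the random lists. Both genes listed for translation initiation factor activity were lower, at -0.57 on contig1 and -0.30 on contig60. A gene listed only for aminoacyl-tRNA editing had a log2 ratio of 0.34 (95% counting interval 0.25 to 0.43) and a gene listed for ribonuclease P, which trims tRNA precursors, 0.53 (0.42 to 0.65).

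All 5 called genes with terms for glycolytic enzymes, which convert glucose to pyruvate, were lower, with a median log2 ratio of -0.74, or 1.67-fold lower. Of the 5 genes, 4 were neighbours on contig113 between 11392 and 16416. The set joins several terms and was put together after the values were seen. The term glycolytic process alone held 3 of the 5 genes, with a median of -0.51 that lay within the 95% range of random lists (-0.77 to 0.35). The gene listed for phosphoglycerate kinase was 1.67-fold lower (log2 ratio -0.74, 95% counting interval -0.76 to -0.72). The gene for triose-phosphate isomerase was 1.85-fold lower (-0.88, -0.91 to -0.86), that for phosphoglycerate mutase 1.71-fold lower (-0.77, -0.79 to -0.76) and that for enolase, listed as phosphopyruvate hydratase, 1.32-fold lower (-0.40, -0.41 to -0.38). The gene for 6-phosphofructokinase on contig127 was 1.42-fold lower (-0.51, -0.52 to -0.49). These genes were abundant, with 42655 to 117571 scaled reads in EA1. On contig113 the gene between 10295 and 11302, beside this row, was not called and had a log2 ratio of 0.11.

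**Figure D2:**
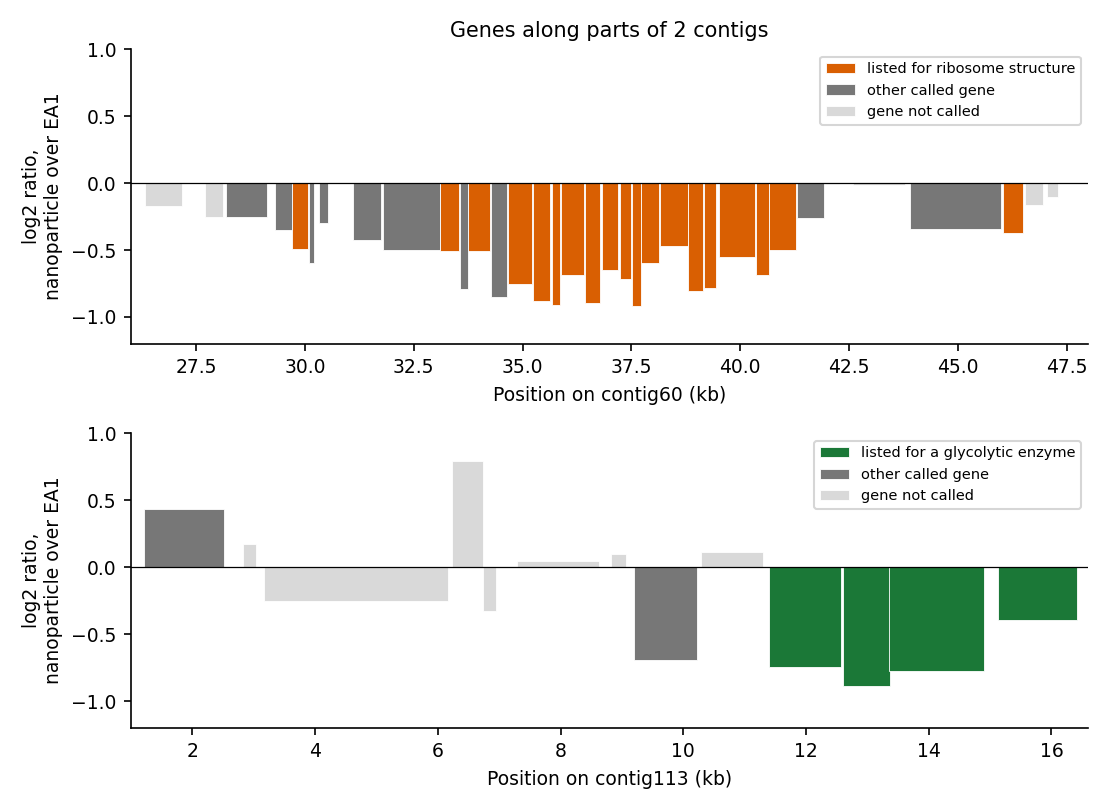
Bars show the log2 ratio of nanoparticle over EA1 for each listed gene, drawn at its position in kb along contig60 (top) and contig113 (bottom). Genes listed for ribosome structure are orange, genes listed for a glycolytic enzyme green, other called genes dark grey and genes that were not called light grey. The genes between 28174 and 41932 on contig60 all lie below 0, as do the 4 glycolytic genes on contig113.

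All 3 called genes listed for cytochrome-c oxidase activity were higher, at log2 ratios of 0.99, 0.45 (95% counting interval 0.43 to 0.47) and 0.37 (0.23 to 0.51). Their median stood at percentile 96.7, within the 95% range of random lists (-0.73 to 0.45). Of 3 called genes listed for electron transfer activity, 2 were higher, at 0.99 (an oxidase gene counted above) and 0.34, and 1 was lower, at -0.34. Both called genes listed for the catalytic part of ATP synthase or of a proton-transporting ATPase complex were lower, at -0.45 (-0.46 to -0.43) and -0.40 (-0.42 to -0.38).

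Transport terms held more higher than lower called genes, and of the transport groups in this paragraph only the phosphotransferase system lay outside the 95% range of random lists. All 5 called genes listed for the phosphoenolpyruvate-dependent sugar phosphotransferase system, which imports and phosphorylates sugars, were higher, with log2 ratios from 0.30 to 0.47 and a median of 0.42, or 1.34-fold. That median stood at percentile 99.0, above the 95% range of random lists (-0.49 to 0.39). The members on contig23 (0.30) and contig33 (0.45) are also listed for regulation of transcription and are counted again in that group. Both are listed for transcription factor binding too, and neither is listed for transport apart from the phosphotransferase term. The term carbohydrate:proton symporter activity, which leaves out both of these members, held 3 called genes, all higher, with the same median of 0.42. It stood at percentile 95.9, within its 95% range (-0.52 to 0.43). All 3 genes listed for amino acid transport were higher, at 0.39, 0.34 and 0.31 (percentile 91.6). Of 6 genes listed for ATPase-coupled transmembrane transport, 5 were higher and 1 lower (percentile 93.1). The highest, on contig73, had a log2 ratio of 0.48 (95% counting interval 0.42 to 0.54). The lower one and one of the higher ones were neighbours on contig60, at -0.36 and 0.39. The gene listed for potassium ion transport was lower, at -0.48 (-0.64 to -0.32). That for protein transport, on contig60, was also lower, at -0.50 (-0.52 to -0.47). Of 16 genes listed as integral components of the membrane, 14 were higher and 2 lower. Their median of 0.36 stood at percentile 99.9, also above the 95% range of random lists (-0.40 to 0.31). That term overlaps the transport and oxidase genes above.

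Among 23 called genes listed for regulation of transcription, 16 were higher and 7 lower, with a median log2 ratio of 0.37 (percentile 99.6). The largest ratio was 0.62 (95% counting interval 0.48 to 0.76), for a gene on contig123 from 9320 to 9730. The smallest was -0.93, for a gene on contig4 from 3927 to 4787 that had 6983 scaled reads in EA1 and 3666 in the nanoparticle library.

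Genes tied to oxidative stress and to metals were few and did not share a direction. The gene listed for catalase, which breaks down hydrogen peroxide, was 1.20-fold higher (log2 ratio 0.27, 95% counting interval 0.25 to 0.29). The gene listed for glutathione peroxidase, which reduces peroxides, was 1.64-fold lower (-0.71, -0.76 to -0.66). No other called gene was listed under response to oxidative stress. The gene listed for cell redox homeostasis was higher, at 0.34, and was already counted under electron transfer activity. A gene on contig49 listed for metal ion transport was 1.44-fold higher (0.53, 0.29 to 0.77). Another gene listed for metal ion binding was higher at 0.37, and both copper-listed genes, already counted under cytochrome-c oxidase, were higher. A transcription regulator on contig142 listed for transition metal ion binding was lower at -0.57. Both genes listed for magnesium ion binding were lower, at -0.29 and -0.40, as were those for manganese ion binding at -0.77 and iron ion binding at -0.36. The manganese gene and the magnesium gene at -0.40 are the phosphoglycerate mutase and enolase genes already counted under glycolytic enzymes.

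Of 3 called genes listed for protein folding, 2, listed as a nucleotide exchange factor of a chaperone and as a heat shock protein binding protein, were lower at -0.38 and -0.36, and the third, a peptidyl-prolyl isomerase, was higher at 0.56. Both genes listed for the flagellum, the rotary motor of swimming, were lower at -0.40 and -0.28. The single gene listed for chemotaxis was higher at 0.86 (95% counting interval 0.55 to 1.19), from 187 scaled reads in EA1 to 341. Its mean of both libraries lay below the abundance floor, where ratios scatter more. Both genes listed for penicillin binding, a property of cell wall synthases, were lower, at -0.48 and -0.41. One gene listed for DNA repair was higher at 0.27 and one for mismatch repair lower at -0.29.

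**Figure D3:**
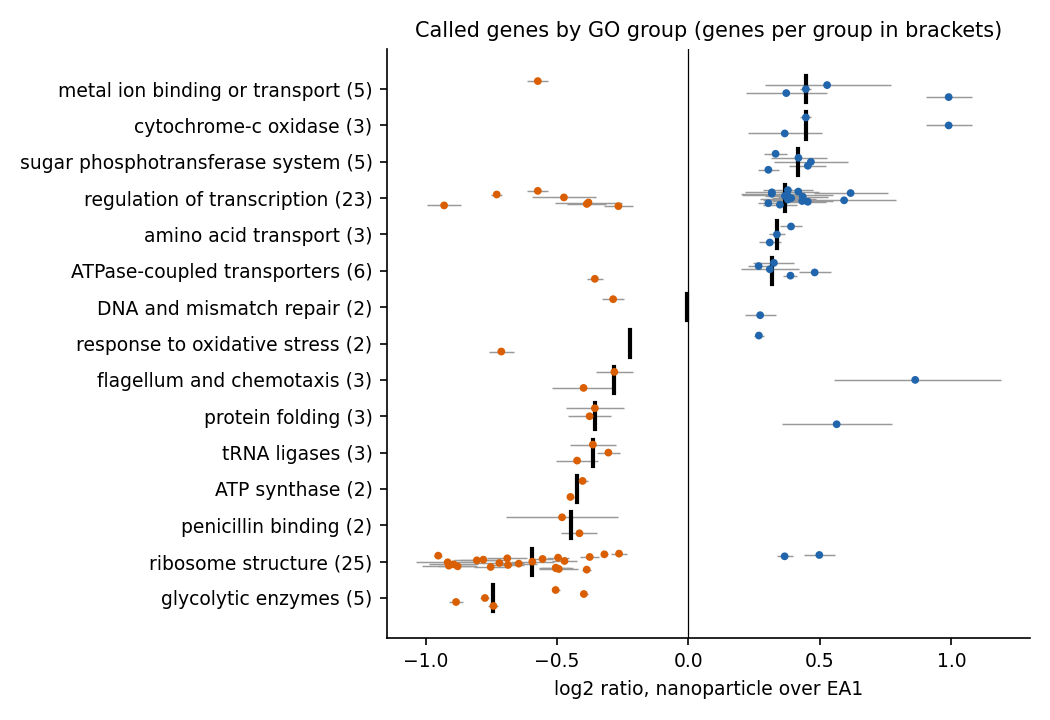
Each point is a called gene placed by its log2 ratio of nanoparticle over EA1, in rows of GO groups with the number of genes in brackets; grey lines are 95% counting intervals and black bars group medians. Points are blue above 0 and orange below. Medians run from -0.74 for glycolytic enzymes and -0.59 for ribosome structure to 0.45 for cytochrome-c oxidase. The metal row holds the terms for metal, copper and transition metal ions, and leaves out the magnesium, manganese, iron and potassium terms, whose genes were all lower.

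In the authors' deposited enrichment table, 16 of 199 GO terms had an adjusted p-value under 0.05. The lowest adjusted p-values in the authors' deposited table were 3.73e-10 for ATP binding, 9.69e-09 for catalytic activity and 3.33e-08 for membrane. The value for membrane is too low for over-representation among the listed genes, as described under other observations. Of the 27 called genes under ATP binding, 13 were higher and 14 lower. Of the 11 under membrane, 9 were higher and 2 lower, with a median log2 ratio of 0.43 above all random lists drawn. In the authors' deposited table, structural constituent of ribosome had an adjusted p of 0.849 and glycolytic process 0.954, and the sugar phosphotransferase system 0.0239. The test behind these values is not given in the sources used here. A low value may therefore mark fewer called genes than expected rather than more.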

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

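The scalings, floors and stricter thresholds named here were chosen before the data were examined, except the totals without the most abundant feature, the trimmed mean for the GO medians, the GO groups, the set without contig60 and the authors' probabilities of 0.9 and 0.95, which were added after the data were seen. The counts of genes at least 2-fold higher and lower (1 and 1) depended on the floor because low genes scatter more: they were 27 and 45 with a floor of 10 reads over both libraries, 20 and 27 with 50 reads (the floor planned for raw counts), 4 and 6 with 200 reads, and 27 and 47 with no floor. Scaling by total reads gave 7 and 0, totals without the most abundant feature gave 2 higher, and the 4-fold rule gave 0 and 0. The median of ratios, the trimmed mean, pseudocounts of 0.1 and 10 and the rule that the counting interval lie beyond 2-fold each gave 1 and 1. The authors' calls (253 higher, 246 lower) fell to 5 and 8 at 2-fold or more, 44 and 67 at a probability of at least 0.9, and 4 and 19 at 0.95, so the share that was lower grew with the threshold. Several of the lower genes at 0.95 were neighbours in the row of ribosomal genes on contig60, so they are not separate differences. Scaling by total reads, which adds 0.28 to each log2 ratio, gave medians of -0.32 for ribosome structure, -0.46 for glycolytic enzymes and 0.70 for the sugar phosphotransferase system. With totals that leave out the most abundant feature the glycolytic median was -0.70. Without the genes of contig60 the ribosome median was -0.29. Of 106 alternative medians over 15 GO groups, 45 could not move: the trimmed mean is the deposited scaling itself, and floors of 10 and 200 reads remove no called gene of the groups. Of the other 61, 41 moved by less than the margin of the counting interval of a typical member, 17 moved by more in the same direction and 3 reversed. The 41 hold all 15 medians under the median of ratios (a shift of -0.01) and all 15 under a pseudocount of 5. Both settings change these ratios very little, so they say little about stability. Totals without the most abundant feature left 11 the same, moved 3 and reversed 1, and total reads moved 13 and reversed 2. Response to oxidative stress went from -0.22 to 0.0551 with total reads, and DNA and mismatch repair from -0.01 to 0.27 with total reads and 0.0300 with totals that leave out the most abundant feature. Both are groups of 2 genes on opposite sides of 0. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. List membership by symbol or product was not run, since the files hold neither, and a stricter adjusted p was not run, since the authors' calls rest on a probability. Counting error was smaller than the observed spread above the floor: by 25% steps of abundance its SD was 0.10, 0.05 and 0.02 against an observed 0.27, 0.25 and 0.24.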

Other observations

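Several other rows of neighbouring called genes also differed between the libraries. A row of 5 neighbouring called genes on contig1 from 55152 to 59832 was lower in the nanoparticle library, with log2 ratios from -1.87 to -0.40. They were of low abundance (median 207 scaled reads), and the 1 gene with a GO term was listed for the flagellum. A row of 6 short neighbouring features on contig102 from 760 to 1243 was lower with a median of -0.60, and none had a GO term. On contig20, 4 genes from 39140 to 42983 were lower with a median of -0.45. Of these, 3 were listed, for carbohydrate metabolism, a UDP-glucose:hexose-1-phosphate uridylyltransferase and a transcription factor. On the other side, 4 genes on contig58 from 48410 to 51370 were higher with a median of 0.58, including one listed for nuclease activity, and 4 genes on contig39 from 31817 to 35754 were higher with a median of 0.49. On contig13, 5 genes from 48866 to 52285 were higher with a median of 0.38.

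The tests reported in this part were chosen after the patterns were seen, and the expected outcome was set down after the value was known for the scaling, short gene, culture, adjacent gene and variance share tests, and before it for genes 3 places apart and for centring by abundance. Lower ribosomal genes: for the 19 genes on contig60 the highest median under the deposited scaling and the alternatives tried was -0.41. Each scaling adds 1 constant to all ratios, at most 0.28 here. The value argues against the choice among these scalings as the whole cause there, and a larger shift was not tried. For the 6 genes elsewhere the highest median was -0.0148, with genes on both sides of 0, which leaves scaling open. The ribosomal genes are short (median 351 bp against 759 bp for all genes). For each of them the median ratio of other genes in its length decile was taken, and these medians had a median of 0.0442. That argues against a loss of short genes as such, while the length of transcripts was not tested. What stays open is whether the nanoparticle or some other difference between the 2 cultures or libraries, such as growth stage at harvest, may account for the pattern: with 1 library per group they cannot be told apart.

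Neighbouring genes moved together. Places were counted after genes below the floor were left out, so adjacent genes here may have such genes between them. Across 2222 pairs of adjacent genes above the floor, the log2 ratios correlated at r = 0.35, against at most 0.09 in 10000 shuffles of the genes. Genes are not independent replicates, and this speaks only against error that is independent at each gene. Genes 3 places apart correlated at 0.20 (highest shuffle 0.09), which argues against reads that span 2 adjacent genes as the whole cause. Centring each abundance decile left 0.35, but it barely moved the ratios and decides nothing. Abundance deciles held a share of 0.00804 of the variance of the log2 ratios, and a trend with abundance cannot give neighbours a correlation above its share, which argues against it as the whole cause. Without contig60 the correlation of adjacent genes was 0.29. Whether the neighbours are transcribed together was not tested, and what made them move together stays open.

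Runs of at least 4 neighbouring called genes of one direction numbered 10, the longest with 27 genes on contig60 from 28174 to 41932, of which 18 were listed for ribosome structure. In 1000 shuffles of the calls over the gene positions the most runs in any shuffle was 3 and the longest run 6 genes.

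The deposited enrichment p-values do not behave as over-representation alone would. With the 3175 listed genes as background, the smallest one-sided over-representation p that 499 called genes allow depends on the size of the term, and is 0.0247 for a term with 2 called genes, yet the authors' deposited table gives 4.04e-09 for transporter activity and 0.000338 for metal ion binding, each with 2 genes. Of the 199 terms, 10 had a deposited p below the limit for their own size, 4 of them among the 16 with an adjusted p under 0.05 in the authors' deposited table. Membrane was 1 of these 4, with 5.01e-10 in the authors' deposited table against a limit of 1.32e-09. For those terms the p cannot come from over-representation against this background. Several of them held only 1 or 2 called genes, such as proteolysis with 1 gene and a deposited p of 0.0322 against a limit of 0.157. Whether the authors' test also counts terms with too few called genes is not known. A low p in that table thus does not show that a term held more called genes than expected. The background used by the authors is not given in the sources used here.

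Of the 3175 listed features, 101 had a length that is not a multiple of 3. The most abundant feature, IE89_17100, was one of them, at 407 bp, and so was the 679 bp feature that ranked 4 in EA1 and 3 in the nanoparticle library. That second feature had a log2 ratio of -0.06.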
